A study of Gossypium arboreum with 8 samples.

How the data were processed

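Single-cell RNA sequencing was carried out on protoplasts, plant cells freed of their walls by enzymes, from lateral root tips of the diploid cotton Gossypium arboreum. Per the labels, 8 samples fall into 4 groups of 2 biological replicates. Control seedlings were kept in liquid medium for 0.5 h, salt1 seedlings in 100 mM NaCl for 0.5 h, salt2 seedlings in 100 mM NaCl for 1 h and salt3 seedlings in 150 mM NaCl for 0.5 h. Droplet libraries were made with the 10x Genomics 3′ chemistry, kit version 3.1, per the labels' protocols. In this chemistry each captured transcript carries a unique molecular identifier (UMI), so that copies made by amplification are counted once, and reads come from the 3′ end of the transcript.

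The deposited values are UMI counts per gene and cell barcode, in 1 matrix of 41034 features and 61095 barcodes. The counts were written by Cell Ranger 5.0.0, per the file headers and the submitters' processing notes, and no normalization is recorded in the file headers. The submitters' processing notes name the genome build mm10, which is a mouse build, whereas the feature identifiers are cotton identifiers. The build and annotation used for counting are otherwise not given in the sources used here, and no coordinates are reported. Each barcode ends in a suffix from 1 to 8. The barcodes that share a suffix are called a barcode library here, and library 1 means the barcodes with suffix 1. Neither the labels nor the file headers tie a suffix to a labelled sample, so the matrix was treated as 1 pooled sample. The 8 libraries are unnamed, and their numbers carry no treatment.

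Comparisons between salt groups and control were planned before the data were examined, as edgeR quasi-likelihood tests on counts summed per sample, over all cells and within cell classes, together with tests of cell shares and of gene lists. They need the group of every cell and were not run. No p-value between treatments is given, and values of libraries are given singly or as a range and median.

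Of the features, 40960 are nuclear gene identifiers that the files do not pair with gene names. None of them matched the gene table of the RefSeq assembly ASM2569848v2 (0 of 40960), while all 74 mitochondrial features did, and the files give these a gene symbol. The 13 lists of cell type markers and 22 lists of stress, hormone and transport genes that had been fixed before the data were examined are defined by gene names and product texts. They had 0 members among the feature names, so none could be scored, clusters carry numbers in place of cell types, and named genes are mitochondrial. The mitochondrial groups below were formed from symbols after the data had been seen.

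Barcodes with at least 500 UMIs and 200 genes were kept. Doublets were called with Scrublet in each library. Its automatic threshold marked 12 of 60646 barcodes (0.0198%), under the 0.5% below which a caller was held not to have worked, so doublets have to be taken as present. The 12 were removed, and removal of the 5% of cells with the highest score in each library was added as an alternative. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 nearest neighbours, a shared-neighbour graph and Leiden clustering at resolution 0.5 were used. No library correction was applied. Since 14 mitochondrial features were among the variable genes, the mitochondrial values of clusters come from a second clustering without them, whose clusters are named M1 to M18. It was added after the data had been seen.

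Expression of a cluster or library is given as CPM, the UMIs of a gene divided by all UMIs of that cluster or library and multiplied by 1000000. A gene was called enriched in a cluster at 50 CPM or more and at least 4 times its CPM in all other cells, with 0.5 counts added to each side. The named genes of a cluster were, by a rule fixed before the data were examined, up to 5 named genes with the largest fold among those with at least 50 CPM and a UMI in at least 10% of its cells. Identifiers without a name were limited to 2 per direction. The higher ones had to meet the same limits on CPM and cells, and the lower ones needed at least 50 CPM in all other cells. Directions were counted in every library with at least 50 cells in the cluster. Intervals are 95% exact intervals, Clopper-Pearson for shares and folds and Poisson for CPM. They cover counting error only. A count of 0 allows up to 3 counts. To compare genes per cell at equal depth, each cell was thinned to 500 UMIs at random.

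The steps were tested on simulated data with the real gene means and depths. In 6000 simulated cells over 41034 genes, all 200 genes raised 8-fold in a simulated group passed the 4-fold rule and 0 others did. The simulated groups, not the clusters, were compared here. This outcome therefore checks the fold calculation alone and does not test enrichment called on clusters. The 3 simulated groups came back as 6 clusters, with 100% of cells in clusters led by their own group and an adjusted Rand index of 0.641. The number of clusters is therefore not a count of cell types.

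Alternatives were resolution 1.0 and 0.3, 4000 variable genes, a minimum of 1000 UMIs and principal components centred per library. Called doublets kept, TMM factors for the spread between libraries, and each library left out were further alternatives. Leaving out a library kept the clusters as they were, without clustering again. Clustering of thinned cells and equal weights of libraries for mitochondrial values were used as well. Python 3.11.15, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, R 4.3.3 and edgeR 4.0.16, the last for TMM factors alone, were used.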

Results

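Transcripts of single protoplasts from cotton lateral root tips were counted to follow the response of root cells to sodium chloride at different doses and times. The labels describe 8 samples in 4 groups, with 2 replicates each of control, salt1, salt2 and salt3. After filtering, 60634 cells with 270385346 UMIs remained, with a median of 2728 UMIs and 1417 genes per cell, and 32279 of 41034 features had at least 1 UMI. Because the 8 barcode libraries are not tied to the labelled samples, no value below is a response to salt.

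The libraries differed in depth and in cell number. Library 1 held 5665 cells with a median of 6254 UMIs, library 2 held 8045 with 1494, library 3 held 8636 with 5250.5 and library 4 held 12320 with 2034.5. Library 5 held 4964 cells with a median of 7790 UMIs, library 6 held 9505 with 2813, library 7 held 6145 with 8120 and library 8 held 5354 with 1358.5. Summed UMIs per library ranged from 7966335 in library 8 to 49544755 in library 1. The median number of genes per cell ranged from 692 in library 8 to 2995 in library 7. With every cell thinned to 500 UMIs, it ranged from 334 in library 8 to 414 in library 1. The 10 most abundant genes took 3.96% of UMIs in library 1 and 11.4% in library 8, with a median of 6.16% over the libraries.

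Mitochondrial transcripts, the only features with gene symbols, made up 0.195% of UMIs, or 0.313% with cells thinned to 500 UMIs. Of these 526065 UMIs, 269210 came from library 1, so that values pooled over libraries lean on it. The gene rpl16, for a protein of the large mitochondrial ribosomal subunit, gave 43.4% of these UMIs and reached 844 CPM over all cells. It was the leading gene in each library, with 35.2% to 60.9% of mitochondrial UMIs. In the pooled counts it was followed by sdh4, for a membrane subunit of succinate dehydrogenase, with 16.5%. The sdh4 share ran from 7.55% in library 2 to 23.7% in library 7, and in libraries 2, 4 and 6 nad5 lay above it. The complex I genes nad5, nad7 and nad2 gave 8.86%, 7.06% and 4.83%, and the ribosomal protein genes rpl10 and rps10 gave 8.59% and 4.61%. Together these 7 genes held 93.8% of mitochondrial UMIs.

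By group, the 10 ribosomal protein features held 56.7% of mitochondrial UMIs, the 11 complex I features 23.5% and the 2 complex II features 16.5%. Over the libraries these shares ran from 50.6% to 72.8%, from 16.7% to 30.02% and from 7.55% to 23.7%. The 7 ribosomal RNA features held 1.78%, with 0.844% to 2.39% over the libraries and the highest share in library 1. The 4 features for cytochrome c maturation held 0.750%, with 0.492% to 0.954%. The 28 transfer RNA features held 0.723%, with 0.180% to 1.74% over the libraries. Complex IV and complex V had few counts, with 348 UMIs over 3 cox features and 183 UMIs over 5 atp features among 526065 mitochondrial UMIs. Their shares ran from 0.0245% to 0.239% and from 0.00813% to 0.0598% over the libraries. The complex III gene cob, for cytochrome b, had 1 UMI. Low counts were not particular to these complexes. The complex I features of nad6, nad4, nad9 and nad3 had 8 to 71 UMIs each, and rpl2, rpl5 and rps7 had 0. The complex II gene sdh3 had 1 UMI, so the complex II share was that of sdh4. Of the 74 features, 14 had over 1000 UMIs and 12 had 0. In all, 10 symbols were listed more than once, among them rrn18 and rrn26, and the UMIs of such copies are uncertain because reads may be shared between them.

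Mitochondrial transcripts were most abundant in library 1. They made up 0.543% of its UMIs (95% interval 0.541 to 0.545), against 0.129% in library 2, 0.194% in library 3, 0.0806% in library 4, 0.114% in library 5, 0.0816% in library 6, 0.0921% in library 7 and 0.0629% in library 8. All 7 leading genes were highest in library 1. There rpl16 reached 2089 CPM, against a median of 472 CPM over the libraries and 222 CPM in library 8, and sdh4 reached 1010.5 CPM against a median of 155 CPM. Cells with over 5% mitochondrial UMIs numbered 451 in library 1, which is 7.96% of its cells (7.27 to 8.70%), out of 499 in all libraries. Libraries 2, 4 and 8 had 0 such cells. Without library 1 the mitochondrial share over all cells was 0.116% and the highest library value was 0.194%. With cells thinned to 500 UMIs, so that every cell counted equally, the share in library 1 was 1.79%.

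**Figure D1:**
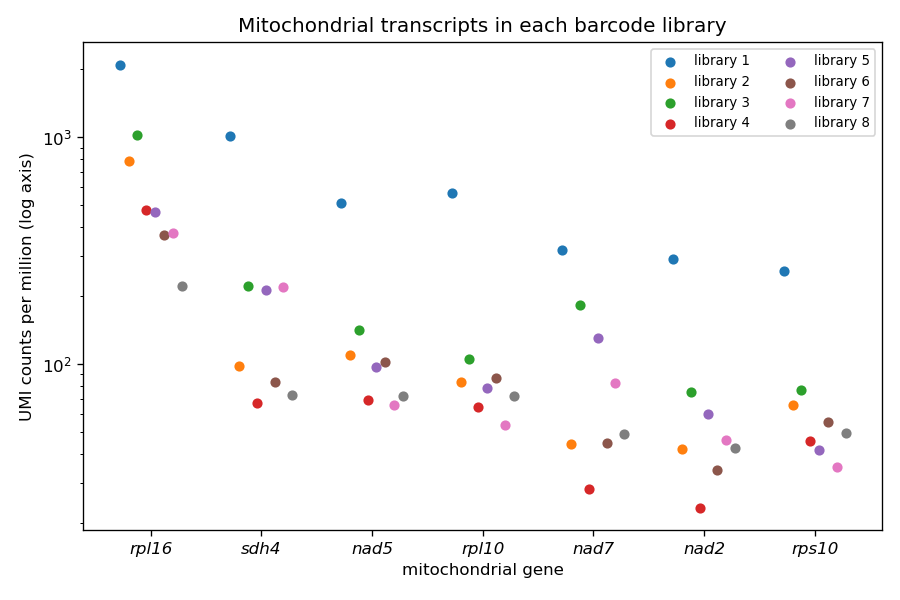
CPM (log axis) of the 7 most abundant mitochondrial genes, with a point for each of the 8 barcode libraries. Every gene is highest in library 1, and rpl16 ranges from 222 CPM in library 8 to 2089 CPM in library 1.

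The cells formed 15 clusters, numbered by size. Cluster 1 held 8971 cells (14.8% of all, 14.5 to 15.1%), cluster 2 held 8903, cluster 3 held 7661 and cluster 4 held 6328, and the smallest, cluster 15, held 577 (0.952%, 0.876 to 1.03%). Of 7998 genes with at least 50 CPM in some cluster, 3015 (37.7%) were enriched in at least 1 cluster and 2019 of these in exactly 1. Cluster 3 had the most enriched genes, 620, followed by cluster 13 with 586 and cluster 14 with 554, and cluster 2 had the fewest, 12. These genes helped to form the clusters, so their number describes the clusters and tests nothing. At resolution 1.0 the number of clusters was 27.

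Among genes with at least 50 CPM and a UMI in at least 10% of a cluster's cells, the largest fold was in cluster 13. This cluster held 1207 cells from all 8 libraries. The gene evm.TU.Ga02G1303 had 169 CPM there (158 to 180) and 0.0867 CPM in all other cells, a 1946-fold difference (1288 to 3086), and was higher in 5 of 6 libraries and lower in 0. It had a UMI in 10.5% of the cells of cluster 13 and in 0.0353% of other cells. The gene evm.TU.Ga04G1679 was 1409-fold higher in cluster 13 (1015 to 2013), in 6 of 6 libraries. In the other direction, evm.TU.Ga08G2626 and evm.TU.Ga10G0987 had 0 UMIs in cluster 9, against 126 and 85.2 CPM in all other cells. Set against the 3 counts that a count of 0 allows over the cluster, they were at least 806-fold and 548-fold lower. Both were lower in 4 of 4 libraries, but 83.7% of the cells of cluster 9 came from library 1, so these folds also hold the difference between library 1 and the others.

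The libraries took unequal parts in the clusters. Clusters 2, 4, 10 and 13 held at least 0.1% of the cells of every library, and the other 11 clusters, with 41685 cells, lacked at least 1 library at that level. Cluster 1 held 31.3%, 36.7% and 20.3% of the cells of libraries 2, 4 and 6, but 0 cells of libraries 1, 3 and 7. Cluster 2 held 45.9%, 41.5% and 41.8% of libraries 3, 5 and 7 and 1.69% of library 1. Cluster 4 held 85.4% of library 8 and at most 8.51% of any other. Cluster 9 held 38.1% of library 1 and at most 2.92% of any other. Cluster 10 held 0.448% to 6.88% of each library. In 5 clusters over 50% of the cells came from a single library.

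**Figure D2:**
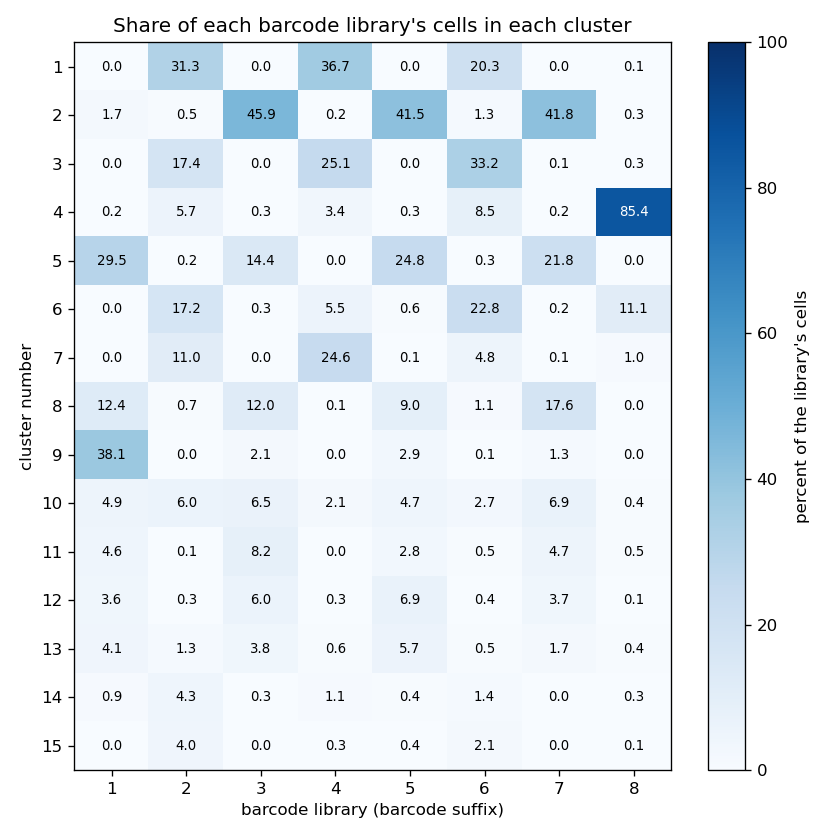
Percent of each barcode library's cells (columns, by barcode suffix) that fell in each of the 15 clusters (rows), with the value written in each field. Cluster 4 holds 85.4% of library 8, and cluster 1 holds 31.3%, 36.7% and 20.3% of libraries 2, 4 and 6 and 0 cells of libraries 1, 3 and 7.

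Mitochondrial transcripts differed between clusters formed without them. In M9, with 2497 cells of which 85.8% came from library 1, they made up 0.605% of UMIs (0.601 to 0.608), 3.69 times the share in all other cells. The value was 6.81 without library 1 and 12.6 with cells thinned to 500 UMIs. M9 held 346 of the 499 cells with over 5% mitochondrial UMIs, which is 13.9% of its cells. Within library 1 the share in M9 was 0.598% against 0.512% in the rest, a 1.17-fold difference. In libraries 3, 5 and 7 it was 4.81, 5.57 and 8.62 times the rest, from 151, 128 and 59 cells with medians of 1099, 1194.5 and 1056 UMIs, far below those libraries' medians. By fold pooled over libraries, the leading named genes of M9 were nad4L with 71.8 CPM (4.84-fold, 4.55 to 5.15), rpl10 with 633 CPM (4.79-fold, 4.69 to 4.89) and sdh4 with 1170 CPM (4.57-fold, 4.50 to 4.64). They were followed by nad2 (4.10-fold) and rrn26 (4.02-fold). All 5 were higher than the rest in 4 of 4 libraries, but over a wide range of folds within libraries: 1.22 to 5.65 for nad4L, 1.23 to 7.99 for rpl10, 1.28 to 8.28 for sdh4, 1.15 to 5.80 for nad2 and 1.06 to 6.11 for rrn26.

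M12, M13, M14 and M15 were also above the rest in every library with at least 50 of their cells. M12 (1513 cells) had 0.353% mitochondrial UMIs and lay 1.24 to 2.08 times above the rest in 5 of 5 libraries. It was led by complex I genes, nad1 at 3.27-fold (2.97 to 3.59) and nad7 at 3.13-fold (2.99 to 3.28), with 1.81 to 7.42 and 2.06 to 3.59 within the 5 libraries. The cells of M12 were shallow, with medians of 2400, 2007.5, 5015, 996 and 2400 UMIs in libraries 1, 3, 5, 6 and 7, each below the median of its library. M13 (1418 cells) had 0.356% and lay 1.55 to 2.16 times above the rest in 4 of 4 libraries. It was led by nad5 at 2.01-fold (1.92 to 2.12) and rpl16 at 1.96-fold (1.91 to 2.00), with 1.86 to 2.38 and 1.86 to 2.09 within the 4 libraries. Its cells were shallow as well, with medians of 1909.5, 2077.5, 2726 and 2724 UMIs in libraries 1, 3, 5 and 7. M14 (1229 cells) was above the rest in 6 of 6 libraries by 1.06 to 1.33 times. Within them rpl16 was at 1.03 to 1.45 times and nad5 at 1.08 to 1.49 times the rest. In contrast, rps10 was higher in 5 of 6 libraries (0.866 to 1.36 times), rpl10 in 3 of 6 (0.932 to 1.34 times) and nad2 in 2 of 6 (0.534 to 1.79 times). M15 (688 cells) was above the rest in 4 of 4 libraries by 1.12 to 1.44 times, although its pooled share, 0.172%, lay below the 0.195% of all cells. The cells of both were also shallower than the median of their library, with medians of 949 to 6295 UMIs over the 6 libraries of M14 and 1172 to 2594 UMIs over the 4 libraries of M15. M3 (7959 cells) was below the rest in 3 of 3 libraries, at 0.703 to 0.775 times, and rpl16 in M3 was at 251 CPM against 883 CPM in other cells, 0.284 times when pooled and 0.442 to 0.527 times within the 3 libraries. In M3 nad5 was at 0.551 times the other cells but higher in 2 of 3 libraries, so its pooled difference did not hold within libraries. In M7 and M11, nad2 and nad7 were higher than the rest in 4 of 4 libraries. The cells of M11 were shallower than their libraries, with medians of 3722, 4481, 3062 and 3342.5 UMIs in libraries 1, 3, 5 and 7. Within libraries nad2 was at 1.17 to 1.71 times the rest in M7 and 1.11 to 1.82 times in M11, and nad7 at 1.19 to 1.53 times and 1.18 to 1.76 times, while the pooled folds were 2.04 and 2.01 for nad2 and 2.02 and 2.09 for nad7.

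**Figure D3:**
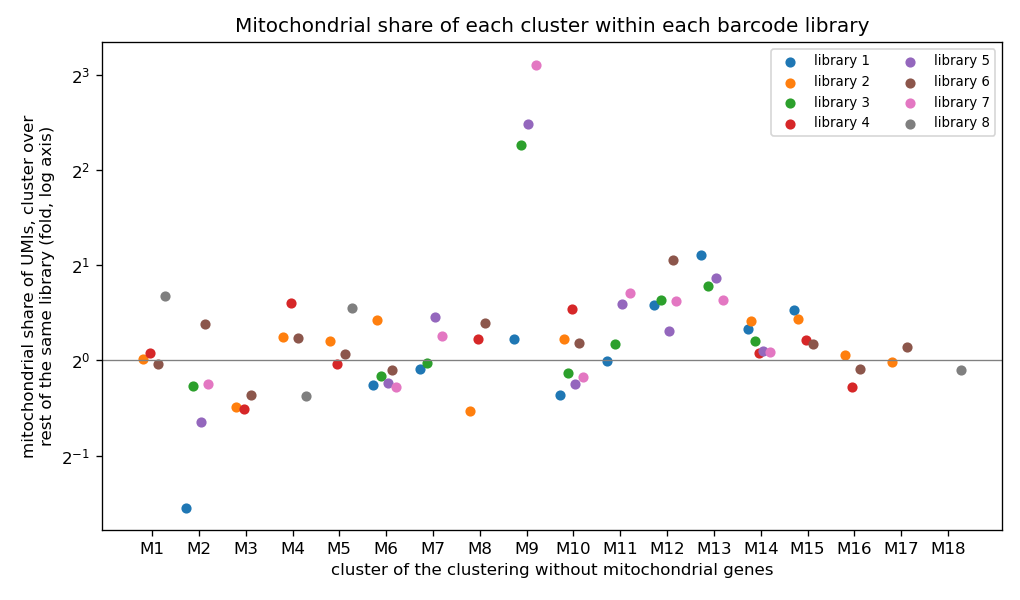
Mitochondrial share of UMIs in each cluster M1 to M18, divided by the share in the other cells of the same barcode library (log axis), with a point for each library that has at least 50 cells in the cluster. M12, M13, M14 and M15 lie above the line at 1 in 5 of 5, 4 of 4, 6 of 6 and 4 of 4 libraries, and M9 ranges from 1.17 in library 1 to 8.62 in library 7.

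Between libraries, CPM summed over all cells differed for a large part of the genes. Of 3603 genes with a mean of at least 50 CPM over the libraries, 2250 (62.4%) differed by 4 times or more between the highest and lowest library and 1036 (28.8%) by 10 times or more, on the scale of log2(CPM + 1). These are extremes over 8 libraries of unknown treatment, with no test. They were not computed with a library left out, so how far they rest on a single library, such as library 8, is not known. The libraries also held unequal shares of the clusters, and cell mix was not separated from expression within cells here.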

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

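No paired analysis was possible because the barcode libraries carry no sample name or replicate number, and for the same reason the alternatives chosen for the treatment comparisons before the data were examined were not run. Keeping list members among the variable genes was not run, as no list had a member. Thinning, clustering without mitochondrial genes, removal of the highest doublet scores and all mitochondrial alternatives were chosen after seeing the data. The count of enriched genes (17 alternatives) and of genes differing 4 times between libraries (3) stayed within 1.5 times, as did the number of clusters except at resolution 1.0 (27). With a library left out, cells kept their main clusters and were not clustered again. The 15 clusters were then fixed, so their number tests nothing there, and the number holding every library could only stay or rise. Clusters with every library numbered 4, but 8 after thinning to 500 UMIs, 6 at resolution 0.3 and after centring, 3 with 4000 variable genes, and 4 to 6 with each library left out. Cells were assigned with an adjusted Rand index of 0.548 (thinned) to 0.863 (highest scores removed) to the main clusters. Keeping the 12 called doublets alone gave 0.759 and 17 clusters. An index of this size therefore arose from a change of 12 cells, and single clusters are not to be taken as stable. The share of cells in clusters lacking a library, 68.7%, was 82.8% and 54.7% at resolution 1.0 and 0.3, 78.8% with 4000 variable genes, 66.1% at 1000 UMIs, 60.4% after centring, 68.1% with called doublets kept, 68.1% without the highest scores, 36.96% after thinning, and 57.8% to 73.0% with each library left out. The mitochondrial share over all cells, in the lowest and in the highest library and the fold in M9 were 0.180%, 0.0560%, 0.481% and 2.93 at 1000 UMIs, and 0.313%, 0.0750%, 1.79% and 12.6 after thinning, which gives shallow cells more weight. Without the highest scores the first was 0.195% and the third 0.552%. With libraries weighted equally the share was 0.162% and the fold 4.63. That fold averaged M9 over libraries 1, 3, 5 and 7 only, but the other cells over all libraries. It therefore also holds the difference between those libraries and the remaining ones, and its rise above the main 3.69 cannot be read as an effect of equal weights. With each library left out the 4 values were 0.116% to 0.218%, 0.0629% to 0.0806%, 0.194% to 0.543% and 3.33 to 6.81; leaving out library 1 gave the lowest overall share and the highest fold. On mean log1p values pooled over libraries M9 lay 2.08 above the rest. As 85.8% of M9 came from library 1, this value also holds the difference between library 1 and the others. For the other shifts the cause was not tested. Library 8 had the fewest UMIs, 7966335.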

Other observations

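Centring per library was chosen before the data were examined, but the bounds of its test were set after its result had been seen. The test of repeated gene copies and the values of the ratio test outside library 1 were likewise chosen after their results, and the other tests after the data had been seen but before their results.

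With all libraries reduced to 7966335 UMIs, the correlation across genes of log2(CPM + 1) ranged from 0.806, between libraries 1 and 8, to 0.985, between libraries 3 and 7. Genes are not independent replicates, so these values describe likeness only. Among libraries 1, 3, 5 and 7 each pair had 0.962 to 0.985, and among libraries 2, 4 and 6 each pair had 0.974 to 0.982. Pairs across these sets had 0.869 to 0.94. The sets were formed after these values had been seen, so the contrast within and across them follows from the choice and tests nothing. Library 8 had 0.909 to 0.942 with libraries 2, 4 and 6 and 0.806 to 0.859 with libraries 1, 3, 5 and 7. The sets also differed in depth per cell, which equal totals do not remove. Median UMIs per cell were 5250.5 to 8120 in libraries 1, 3, 5 and 7 and 1358.5 to 2813 in libraries 2, 4, 6 and 8. No treatment is known for any of these libraries. Between 4 and 29 barcode sequences were shared by each of the 28 pairs of libraries.

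Clusters were filled almost only by some libraries, with 68.7% of cells in clusters that held under 0.1% of the cells of at least 1 library. After centring, which would remove a shift shared by all cells of a library, 60.4% of cells lay in such clusters. The bounds for this value were set after it had been seen. Centring also moves libraries of unlike cell mix against each other, and cluster 4 held 85.4% of library 8. Whether a shared shift was the cause is therefore not decided. A difference in depth stays open as part of the cause: after thinning to 500 UMIs the value was 36.96%, between the bounds of 10% and 50% set beforehand, and thinning also removes information that separates cells. The treatments named in the design, and differences in which cells survived protoplasting, may contribute and were not tested.

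Mitochondrial UMIs fell on few genes. Reads lost between gene copies listed among the mitochondrial features are argued against, because 69.7% of the 33 protein-coding genes that are listed once (23 genes) held under 1% of the UMIs of rpl16. Reads shared with copies in the nuclear genome were not tested and stay open. Gene length is argued against as the main source, with a Spearman rho of 0.150 between length in the reference table and UMIs over these 33 genes. No interval was computed for this rho, so a weaker relation with length stays open. A single source of mitochondrial RNA with fixed proportions, such as free RNA, would keep rpl16 in a fixed ratio to the other mitochondrial UMIs, but in library 1 the lower bound of the largest ratio over 11 clusters was 2.52 times the upper bound of the smallest. This value was 1.88, 2.24, 2.16, 1.75, 2.14, 2.16 and 1.42 in libraries 2 to 8, and it sets extremes against each other, so a share of free RNA in these counts stays possible. Which transcripts carry an adenine-rich stretch that the 3′ chemistry can capture is a candidate explanation that was not tested, and no biological explanation was tested.

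Genes with consecutive numbers in their identifiers were often enriched in the same cluster. Of 374 such pairs with both genes enriched, 117 (31.3%) had the same cluster as their highest, against a median of 37 and a highest value of 60 in 10000 shuffles of the clusters among the 3010 enriched nuclear genes. Reads of 1 gene counted to both neighbours in a fixed proportion, as the only source of the second gene's counts, would keep the count ratio fixed. This is argued against for 79 of 114 pairs (69.3%), in which the ratio differed by over 4 times between clusters. The test sets extremes over clusters against each other. Where the second gene also has reads of its own, the ratio can vary although shared reads set its highest cluster. Counting of this partial kind therefore stays open for all pairs. Tandem copies of a gene that kept a shared pattern, and shared regulation of neighbours, may also account for the excess; these need gene sequences and were not tested.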
